A study of Mus musculus with 16 samples.

How the data were processed

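RNA from the myocardium of 16 mice, 500 ng of total RNA each, was hybridised to 1 Affymetrix array per mouse, 4 mice in each of 4 groups (2 genotypes by 2 diets). The deposited table holds log2 values for 34351 probe sets. The base of the logarithm is not given in the sources used here and was taken as 2. The authors put the arrays on 1 scale and subtracted each probe set's median over the 16 arrays, so that every probe set has a median of 0 within 1e-06 and no signal level or background is left. The sign is not given there either and was taken as positive for higher expression. That 23 values lie above 2 and 17 below -2, with extremes of 5.50 and -2.80, does not settle it. The software, background correction, summarisation and normalization method used upstream are not given in the sources used here. Precision is limited by the number of arrays.

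Probe sets with exactly 1 gene symbol (23521) were used, and those with several symbols (1814) or none listed (9016) were left out except in 1 other setting. Symbols were checked by gene ID against RefSeq genes of GRCm38.p6, which changed 0 symbols and had no match for 193 probe sets. This gave 22180 genes, of which 1082 have more than 1 probe set. The plan let the probe set with the highest mean stand for a gene, which has no meaning for centred values. The mean of all probe sets of the gene, which was to be tried beside it, was used in its place, and the highest-mean rule was run for comparison.

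Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group, 12 residual and 4.16 prior degrees of freedom and two-sided moderated tests. Benjamini-Hochberg adjustment ran over all genes tested, with adjusted p under 0.05 as the threshold and no fold minimum. The 7 comparisons were Clock against WT on each diet, HFD against chow in each genotype, their interaction, and the averages of the genotype and of the diet differences. An error given after ± is the standard error of the fit unless it is called SD. The fit takes 1 spread per gene over all groups, also where the groups differ in spread.

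The 23 pathway lists and 18 cell type lists were tested with camera at its preset correlation of 0.01, adjusted within each kind of list, and also with an estimated correlation and with fry. Of 779 list members 707 were matched. Members of a list were counted over all genes and adjusted over the list alone. The pathway lists cover E-box and REV-ERB-repressed clock genes, fatty acid oxidation, PPAR targets, the respiratory chain, glucose use, branched-chain amino acids, cholesterol, lipogenesis, stretch-responsive cardiac genes, excitation, extracellular matrix, inflammation, interferon, antigen presentation, heat shock, endoplasmic reticulum stress, antioxidants, glucocorticoid and FOXO targets, insulin and AKT signalling, proliferation, immediate early genes and autophagy.

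The genes named were set by a rule. It names Clock and the members of both clock lists in every comparison. It names per comparison the 8 genes that rose most and the 8 that fell most among those past the threshold whose 2 groups of 4 do not overlap, without predicted genes, and where fewer than 5 pass, the 5 with the smallest p. It names up to 4 passing members of each list with the largest change, and for a list called with no passing member the 2 with the smallest p. For the averages it names the 5 highest and 5 lowest not yet named. Other list members named were chosen after their values were seen. The groups, tests, lists, naming rule and other settings to try were fixed before the data were examined.

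The other settings were all probe sets, the highest-mean probe set, eBayes with trend and robust, array weights, a repeated quantile normalization, a fit of only the 8 arrays compared, a replicate block and leaving out each array. The filter on dim genes was not run, since centred values hold no levels. The fit was tested on simulated data with 22180 genes, 10 data sets and 200 changed genes each. For Clock against WT on HFD it recovered 29.2% of the genes changed by log2 0.25, 90.2% of those changed by 0.5 and 99.5% of those changed by 1, with 5.14% to 5.49% of calls false. A list of 20 genes, shifted by 0.1 only where genes were changed, had a camera p under 0.05 in 10 of 10 data sets at each size of change. An unshifted list of 20 genes had one in 1 of 10 data sets with no gene changed, in both comparisons simulated, and in 0 of 10 at each size of change. Genes were simulated independently of each other. These list results therefore do not show how camera at its preset correlation behaves where the genes of a list are correlated. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.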

Results

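Transcripts were measured in the myocardium of 16 C57Bl/6J mice, 4 in each of 4 groups: wild-type (WT) mice and mice homozygous for the delta 19 allele of Clock (below, Clock mice or hearts). Each genotype was fed standard chow or a high-fat diet (HFD). CLOCK is the partner of BMAL1 in the transcription factor that drives the circadian clock, and the delta 19 allele gives a protein that still binds BMAL1 but activates transcription poorly. The mice ate their diet for 24 weeks and were 32 weeks old when the hearts were taken, 7 hours after lights on. All values are from this 1 time of day, so a rhythm that is shifted and a rhythm that is flattened give the same kind of difference here. The design asks what the clock mutation and the diet each do to the transcripts of the heart, and whether the mutation alters what the diet does.

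Each heart was read on 1 Affymetrix array, with 34351 probe sets of which those with a single gene symbol gave 22180 genes. The deposited values are log differences from each probe set's own median over the 16 arrays, so hearts can be compared with each other but the abundance of a transcript is unknown. The base of the logarithm and the sign are not given in the sources used here, and were taken as 2 and as positive for higher expression. Differences below are on that log2 scale, ± the standard error of the limma fit, with 4 mice in each group. The medians of the arrays lay between -0.00154 and 0.00281 and their standard deviations between 0.111 and 0.159. All 16 arrays correlated more with their own group than with the other groups. Clock chow replicate 4 had the lowest mean correlation with its own group (0.00508, against -0.0525 with the other groups) and the lowest array weight (0.656). The first principal component held 19.2% of the variance and set the Clock hearts apart from the WT hearts. The second held 13.3% and ran from chow to HFD. The number of arrays limits the precision of every value, and comparisons that share a group share its arrays.

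The transcript of the mutated gene itself, Clock, lay at -0.08 ± 0.19 (SD, n = 4) in WT hearts on chow and at -0.40 ± 0.14 (SD, n = 4) in WT hearts on HFD. In Clock hearts it lay at 0.08 ± 0.05 (SD, n = 4) on chow and at 0.02 ± 0.03 (SD, n = 4) on HFD. On HFD it was higher in Clock than in WT hearts by 0.42 ± 0.08 (adjusted p = 0.00965), and on chow the difference of 0.17 ± 0.08 did not pass (adjusted p = 0.529). The mutation removes 1 exon and leaves the rest of the transcript, and which part the probe set reads is not given in the sources used here, so this transcript says little about the genotype of a heart. The target genes of CLOCK say more: Dbp was lower in each of the 8 Clock hearts than in any of the 8 WT hearts.

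**Figure D1:**
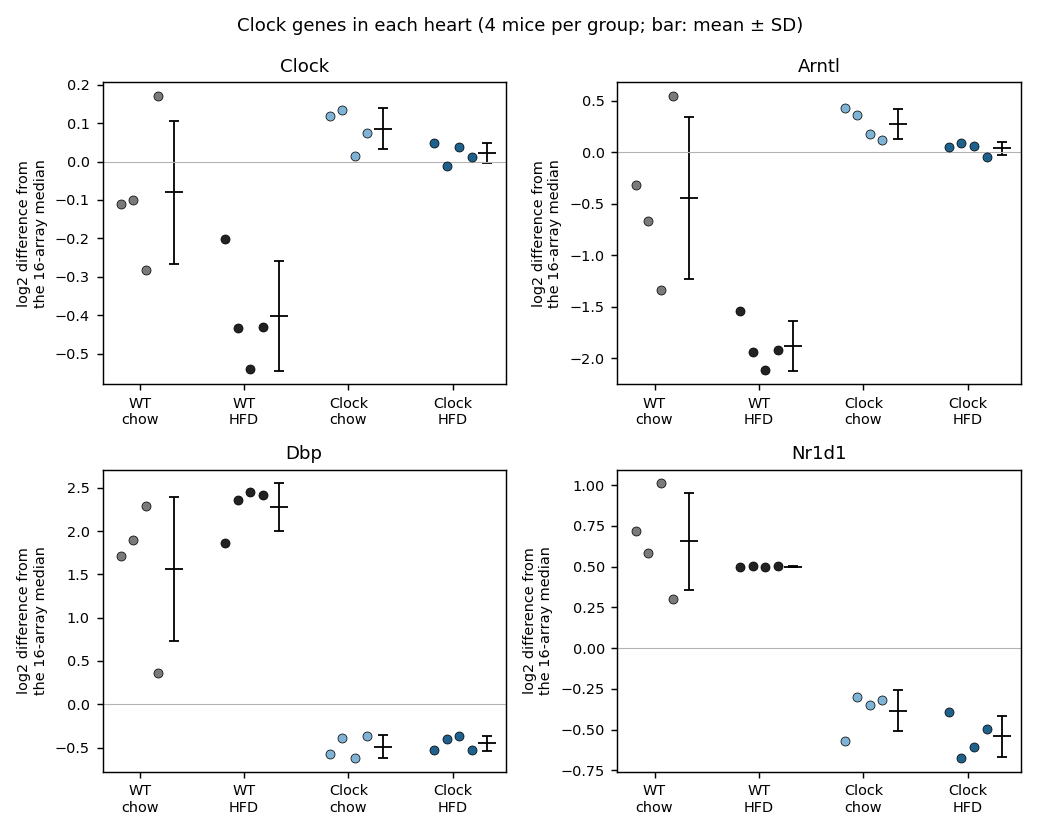
Log2 difference from the 16-array median of Clock, Arntl, Dbp and Nr1d1 in each heart (points), with the mean and standard deviation of the 4 mice per group (bars). Dbp and Nr1d1 lie lower in the Clock hearts on both diets, and Arntl lies lowest in the WT hearts on HFD, at -1.88 ± 0.24.

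On chow, 5 of 13 clock genes that CLOCK and BMAL1 switch on through E-boxes were lower in the Clock hearts, and 8 did not pass. Dbp, a clock-controlled transcription factor, fell by 2.05 ± 0.27 (4.14-fold, adjusted p = 0.00154). Nr1d2 and Nr1d1, which encode the REV-ERB repressors of the clock, were lower by log2 -1.13 ± 0.16 and -1.04 ± 0.11. The hearts also had less Ptgds, the prostaglandin D2 synthase (-1.93 ± 0.22), and less of the carboxylesterase gene Ces1d (-1.63 ± 0.19). They had less Bdh1, the mitochondrial enzyme that oxidises the ketone body beta-hydroxybutyrate (-0.98 ± 0.12). Among 109 genes that differed at adjusted p under 0.05, 53 were higher and 56 lower in Clock hearts.

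Of the 13 measured clock genes driven through E-boxes, 5 fell in Clock hearts on chow, 8 did not pass and 12 fell when p was adjusted over the list alone. Per3 (-0.79 ± 0.15) and the deubiquitinase gene Usp2 (-0.70 ± 0.12) were the others that fell. The list as a whole was lower (adjusted p = 7.02e-20), with adjusted p = 0.0581 with an estimated correlation. Of the 7 clock genes repressed by REV-ERB through RORE elements none passed, and 2 were higher and 1 lower when p was adjusted over the list alone. This list did not pass (adjusted p = 0.112). Without WT chow replicates 2 and 4 together it was higher with 1 gene rising (adjusted p = 0.00330), and so were neutrophil markers (0.0145). Here and below, that setting leaves only 2 WT chow mice, so a call lost in it may reflect lost precision. A call gained in it rests on those 2 mice. Arntl, which encodes BMAL1, was 0.72 ± 0.26 higher in Clock hearts on chow without passing (adjusted p = 0.309). Among genes outside the clock, the largest rises were Plac9a (1.15 ± 0.08) and Slc17a7, the vesicular glutamate transporter (0.98 ± 0.12). Next came Slc41a3, a magnesium transporter (0.77 ± 0.13), and Ankrd23, a stretch-responsive protein of the sarcomere (0.71 ± 0.13). The calcineurin inhibitor gene Rcan1 (0.70 ± 0.14), Lrtm1 (0.67 ± 0.06), the gelatinase gene Mmp9 (0.60 ± 0.10) and the potassium channel gene Kcnd2 (0.60 ± 0.10) rose too. Ano4, of the anoctamin family of scramblases and channels, fell by 1.20 ± 0.06 and had the smallest adjusted p of all genes (5.27e-08), and Prxl2a fell by 0.96 ± 0.07.

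Matrix and stromal genes were higher in the Clock hearts on chow as sets. In the extracellular matrix list 2 of 34 measured genes rose, Mmp2 (0.54 ± 0.10) and the fibronectin gene Fn1 (0.43 ± 0.08), and 13 rose when p was adjusted over the list alone. That list was higher (adjusted p = 1.03e-09), with adjusted p = 0.0581 with an estimated correlation. Markers of fibroblasts (adjusted p = 1.05e-08) and of endothelial cells (adjusted p = 1.60e-05) were higher although none of the 14 genes in either list passed singly. Both lists had adjusted p = 0.221 with an estimated correlation. Over the list alone, 8 fibroblast and 3 endothelial markers rose. Lum (0.37 ± 0.09) and Gsn (0.32 ± 0.08) had the smallest p among the fibroblast markers, and Emcn (0.21 ± 0.06) and Tek (0.26 ± 0.08) among the endothelial ones. The fibroblast and matrix lists both hold Dcn, Lum, Col1a1, Col1a2, Col3a1 and Postn, so their calls are not independent.

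In the fatty acid oxidation list 2 of 19 genes fell, the isomerase genes Eci2 (-0.29 ± 0.06) and Ech1 (-0.25 ± 0.05), and 4 over the list alone. This list was lower (adjusted p = 0.0165, but adjusted p = 0.696 with an estimated correlation). This call was lost without WT chow replicate 1 (adjusted p = 0.185) or 3 (0.0874) or Clock chow replicate 4 (0.0611). Without WT chow replicates 2 and 4 together it had adjusted p = 7.61e-06, with 0 genes falling. The 69 subunits of the respiratory chain (adjusted p = 7.47e-05), the autophagy list (adjusted p = 0.00683) and the endoplasmic reticulum stress list (adjusted p = 0.0165) were higher as sets. With an estimated correlation they had adjusted p = 0.581, 0.222 and 0.153. In the stress list the stress-induced gene Ddit3 rose (0.42 ± 0.08, 1 of 21 and 2 over the list alone), and the call was lost without WT chow replicate 1 (0.0600). Without those 2 arrays all 3 calls of higher lists were lost, with adjusted p = 0.298 for the respiratory chain and for autophagy and 0.0633 for the stress list. No respiratory subunit and no autophagy gene passed singly, 1 and 0 rose over the list alone, and Cox7a1 (0.22 ± 0.05) and Atg12 (0.18 ± 0.07) had the smallest p. The cholesterol synthesis genes Hsd17b7 (-0.70 ± 0.12) and Fdft1 (-0.39 ± 0.08), the potassium channel subunit gene Abcc9 (-0.32 ± 0.06) and the lipocalin gene Lcn2 (-0.61 ± 0.12) fell, and Ddit4, an inhibitor of mTOR signalling, rose (0.55 ± 0.12).

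Of the 109 genes, 108 had no overlap between the 4 Clock and the 4 WT hearts. Over all genes tested 1099 (4.95%) had none, against 2.86% by chance. The count was 49 without Clock chow replicate 1 or WT chow replicate 2, 64 without Clock chow replicate 3 and 71 without Clock chow replicate 2. Of the named genes, 14 of 28 kept adjusted p under 0.05 whichever array was left out, among them Dbp, Nr1d1, Nr1d2, Ptgds, Ces1d, Ano4 and Plac9a.

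On HFD, clock genes driven through E-boxes were lower and Arntl was higher in Clock than in WT hearts. Dbp fell by 2.73 ± 0.27 (6.62-fold, adjusted p = 5.47e-05) and Arntl rose by 1.92 ± 0.26 (3.77-fold, adjusted p = 0.000746). Cdkn1a, the cell cycle inhibitor p21, rose by 1.76 ± 0.23, and Cldn5, the tight junction protein of endothelium, rose by 1.21 ± 0.17. Ces1d fell by 2.55 ± 0.19. In all, 422 genes differed, 251 higher and 171 lower in Clock hearts.

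Of the 13 clock genes driven through E-boxes, 11 fell in Clock hearts on HFD (11 over the list alone). The list was lower both with the preset correlation (adjusted p = 9.27e-25) and with an estimated one (adjusted p = 0.0478). Nr1d2 (-1.45 ± 0.16), Ciart (-1.35 ± 0.25), Per3 (-1.34 ± 0.15) and Wee1 (-1.05 ± 0.15) fell most after Dbp. Nr1d1, Usp2, Bhlhe41, Cry2, Hlf and Tef fell by 0.35 to 1.04, and Per1 (-0.18 ± 0.27) and Bhlhe40 (-0.38 ± 0.19) did not pass. The 2 probe sets of Tef disagreed, at -0.74 and 0.05, so its fall rests on 1 of them. Of the 7 genes repressed by REV-ERB, Arntl, the repressor gene Nfil3 (0.64 ± 0.13) and Clock rose and Rora fell (-0.34 ± 0.05), with 3 and 1 over the list alone. That list was higher (adjusted p = 0.0392, but adjusted p = 0.277 with an estimated correlation). The call was lost without WT HFD replicate 1 (0.0723) or 4 (0.114) or Clock HFD replicate 1 (0.118) or 3 (0.0551).

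In the extracellular matrix list 9 of 34 genes rose on HFD and 16 over the list alone, and 4 with the immediate early gene mean as a covariate. Thbs1, a matricellular regulator of TGF-beta (1.16 ± 0.27), the basement membrane collagen gene Col4a1 (0.62 ± 0.10), the membrane-bound metalloproteinase gene Mmp14 (0.54 ± 0.08) and Fn1 (0.48 ± 0.08) rose most. Thbs1 was lowest in WT HFD replicate 4 (-1.88), which also had the lowest early gene mean. The list was higher (adjusted p = 1.99e-09), with adjusted p = 0.0640 with an estimated correlation. Of 14 endothelial markers 4 rose and 10 over the list alone, among them Cldn5, Robo4 (0.44 ± 0.09) and Esam (0.39 ± 0.07). As a set they were higher (adjusted p = 3.72e-08, but adjusted p = 0.132 with an estimated correlation). The fibroblast list was higher with no gene passing singly and 5 over the list alone (adjusted p = 0.00306, but adjusted p = 0.681 with an estimated correlation). This call was lost without WT HFD replicate 3 (0.0520) or Clock HFD replicate 3 (0.109), or with that covariate (0.0526).

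Rcan1 (1.08 ± 0.14), the actin crosslinker gene Flnc (0.35 ± 0.07) and Uck2 (0.31 ± 0.06) rose among 18 fetal and stretch-responsive cardiac genes. Over the list alone 5 rose and 2 fell, and the list was higher (adjusted p = 0.000947, but adjusted p = 0.377 with an estimated correlation). Of 22 genes of glucose use Pfkp (0.65 ± 0.10) and Hk1 (0.44 ± 0.07), which encode a phosphofructokinase and a hexokinase, rose. Over the list alone 5 rose and 1 fell, and that list was higher too (adjusted p = 0.00239, but adjusted p = 0.532 with an estimated correlation). The chaperone genes Hsph1 (0.66 ± 0.15) and Hsp90aa1 (0.48 ± 0.12) rose among 20 heat shock genes, and 5 over the list alone. This list was higher (adjusted p = 0.000172, but adjusted p = 0.277 with an estimated correlation). Sod3, the extracellular superoxide dismutase (0.48 ± 0.09), Nqo1 (0.41 ± 0.09) and Txnrd1 (0.25 ± 0.06) rose and Gsta3 fell (-0.39 ± 0.07) among 24 antioxidant genes. Over the list alone 3 rose and 2 fell, and the set was higher (adjusted p = 0.0151, but adjusted p = 0.277 with an estimated correlation). That call was lost without WT HFD replicate 1 (0.0511) or 4 (0.0603).

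Immediate early genes, which respond to stimulation within minutes, were higher as a set in Clock hearts on HFD (adjusted p = 4.44e-05, but adjusted p = 0.479 with an estimated correlation). Of 25, Egr2 rose (0.47 ± 0.09) and Ier3 fell (-0.64 ± 0.11), with 2 higher and 1 lower over the list alone. The mean of this list ran from -0.66 to 0.40 within the 8 HFD hearts, and with it as a covariate 280 genes differed in place of 422. Since the list itself differed by genotype, the covariate can take away part of the genotype difference, so a call lost with it does not show the cause. Lost with this covariate were the lists of REV-ERB-repressed genes (adjusted p = 0.0614), fatty acid oxidation (0.118) and antioxidants (0.154). The respiratory chain (adjusted p = 0.00268), in which Cox7a1 rose (0.25 ± 0.05), and the autophagy list (adjusted p = 0.000362), in which none of 22 genes passed, were higher again, and fatty acid oxidation was lower with none of 19 genes passing (adjusted p = 0.0345). Over the list alone 1 respiratory subunit and no autophagy gene rose and 2 fatty acid oxidation genes fell. With an estimated correlation these had adjusted p = 0.569, 0.117 and 0.569. Fatty acid oxidation was lost without WT HFD replicate 2 (0.0519) or 4 (0.164) or Clock HFD replicate 1 (0.210), 2 (0.0790) or 3 (0.0551). Among the other genes that rose were Ddit4 (0.89 ± 0.12), the stress transcription factor gene Atf4 (0.42 ± 0.08), Kcnd2 (0.64 ± 0.10), the pacemaker channel gene Hcn2 (0.50 ± 0.11) and the potassium channel gene Kcna5 (0.40 ± 0.09). The adhesion molecule gene Vcam1 (-0.54 ± 0.10), the cytokine gene Il33 (-0.45 ± 0.10), Fdft1 (-0.47 ± 0.08) and the amino acid catabolism genes Dbt (-0.28 ± 0.06) and Mmut (-0.22 ± 0.05) fell.

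Of the 422 genes, 414 had no overlap between the groups. Over all genes 1972 (8.89%) had none, against 2.86% by chance. The count was 241 without Clock HFD replicate 2 and 266 without Clock HFD replicate 3. Of the named genes, 40 of 58 kept adjusted p under 0.05 whichever array was left out, among them Arntl, Cdkn1a, Cldn5, Col4a1 and Dbp.

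The genotype differences on the 2 diets, which share no array, held many genes in common. Of the 109 genes on chow and the 422 on HFD, 73 were called in both. Of these 31 were higher and 42 lower in Clock hearts and 0 in opposite directions, where independent lists would share 0.60 and 0.43. Both tests of a gene use the same estimate of its spread, which can raise the overlap but does not favour equal directions. Over all genes the differences correlated at r = 0.52 (rho = 0.35), a value across genes, which are not independent replicates. Slc17a7, Slc41a3, Ankrd23 and Rcan1 were among the 8 largest rises on both diets, and Dbp, Ptgds, Ces1d, Ano4 and Nr1d2 among the 8 largest falls.

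Averaged over the diets, the mutation changed 861 genes, 541 higher and 320 lower in Clock hearts, and 507 without WT chow replicates 2 and 4 together. The E-box genes (11 of 13 fell, 12 over the list alone) and the extracellular matrix genes (13 of 34 rose, 21 over the list alone) were the lists that passed both with the preset correlation (adjusted p = 7.25e-26 and 1.95e-12) and with an estimated one (adjusted p = 0.0246 for each). Mmp2 (0.50 ± 0.07), Col4a1 (0.46 ± 0.07), Fn1 (0.45 ± 0.06) and the lysyl oxidase-like gene Loxl1 (0.34 ± 0.06) rose most among the matrix genes. Endothelial markers rose in 7 of 14 cases (10 over the list alone, adjusted p = 2.92e-09, but adjusted p = 0.0884 with an estimated correlation). Fibroblast markers rose in 6 of 14 (8 over the list alone, adjusted p = 2.01e-07, but adjusted p = 0.306 with an estimated correlation). Of these genes 8 matrix, 3 endothelial and 0 fibroblast ones rose without WT chow replicates 2 and 4 together, and the sets kept adjusted p = 1.43e-11, 9.59e-09 and 2.06e-06. Macrophage markers did not move with them (0 of 14 rose or fell, adjusted p = 0.617).

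**Figure D2:**
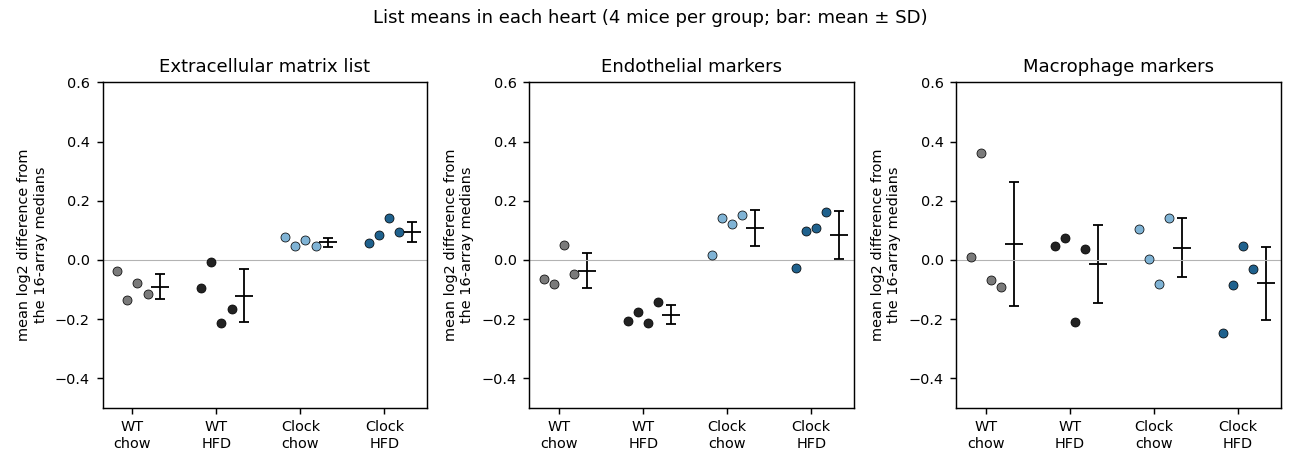
Mean over the measured genes of the extracellular matrix, endothelial and macrophage lists in each heart (points, log2 difference from the 16-array medians), with the mean and standard deviation of the 4 mice per group (bars). The matrix list lies above 0 in all 8 Clock hearts and below 0 in all 8 WT hearts, and the highest macrophage value, 0.36, is that of WT chow replicate 2.

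Of 19 fatty acid oxidation genes 4 fell in this average (6 over the list alone), among them Cpt1a, which controls entry of fatty acids into mitochondria (-0.35 ± 0.08). The list was lower (adjusted p = 0.0105, but adjusted p = 0.539 with an estimated correlation). Pfkp (0.51 ± 0.07) and Hk1 (0.36 ± 0.05) rose and Pdk1 fell (-0.18 ± 0.05) among the genes of glucose use (4 and 1 over the list alone). Cox7a1 rose (0.23 ± 0.03) among the respiratory subunits (3 rose and 1 fell over the list alone). Lamp1 (0.21 ± 0.05), Atg12 and Becn1 rose in the autophagy list (4 over the list alone). These lists were higher (adjusted p = 0.0218, 2.87e-05 and 8.89e-05), with adjusted p = 0.563, 0.407 and 0.0710 with an estimated correlation. The insulin and AKT list was higher with Igf2r, Irs1 and Akt2 rising by 0.18 to 0.19 (3 of 25, and 4 rose and 1 fell over the list alone, adjusted p = 0.0465, but adjusted p = 0.504 with an estimated correlation). Scd4 (-0.80 ± 0.17) and Dgat2 (-0.35 ± 0.07) of triglyceride synthesis, Hsd17b7 (-0.64 ± 0.08) and Fdft1 (-0.43 ± 0.05) fell.

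The fetal and stretch-responsive list was mixed: Rcan1 (0.89 ± 0.10), Mybpc2, Flnc and Uck2 rose while Ankrd1 (-0.77 ± 0.16) and Myh7, the beta myosin heavy chain (-0.61 ± 0.14), fell (6 and 3 over the list alone). The set was higher (adjusted p = 0.0465, but adjusted p = 0.563 with an estimated correlation). Higher lists were also those of heat shock (2 of 20 rose, 7 rose and 1 fell over the list alone, adjusted p = 0.00210), endoplasmic reticulum stress (4 of 21, 5 over the list alone, 0.0428) and antioxidants (3 of 24 rose and 1 fell, 6 and 3 over the list alone, 0.0465). So were those of immediate early genes (1 of 25 rose and 1 fell, 2 and 1 over the list alone, 0.00248) and REV-ERB-repressed clock genes (3 of 7 rose and 1 fell, also over the list alone, 0.0289). With an estimated correlation these 5 lists had adjusted p = 0.347, 0.224, 0.347, 0.563 and 0.224. Proliferation genes were lower with 0 of 28 passing, also over the list alone (adjusted p = 0.0218, but adjusted p = 0.224 with an estimated correlation). Among these lists, leaving out 1 array ended the call for proliferation (WT chow replicate 2, adjusted p = 0.0627), immediate early genes (Clock HFD replicate 3, 0.0606) and REV-ERB-repressed genes (WT HFD replicate 4, 0.0503, or Clock HFD replicate 1, 0.0528). It ended that of glucose use, insulin, stretch-responsive genes, endoplasmic reticulum stress and antioxidants with 5, 10, 12, 7 and 9 of the 16 arrays (highest adjusted p 0.0809, 0.156, 0.169, 0.0684 and 0.173). Without WT chow replicates 2 and 4 together the same 5 lists were lost (adjusted p = 0.517, 0.224, 0.168, 0.0758 and 0.0854), and so was proliferation (0.0559). With the immediate early gene mean as a covariate antioxidants were lost (0.195).

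Genes named for this average alone were Trp53i11 (0.63 ± 0.10), Vwa3a (0.60 ± 0.08) and Abra, an actin-binding activator of stretch-responsive transcription (0.55 ± 0.12), which rose. The kinase gene Mylk4 (-0.95 ± 0.08), the lubricin gene Prg4 (-0.88 ± 0.10), the coenzyme Q-binding gene Coq10b (-0.83 ± 0.09) and the flavin monooxygenase gene Fmo2 (-0.78 ± 0.06) fell. The other pathway lists, which cover PPAR targets, branched-chain amino acid catabolism, cholesterol, lipogenesis, cardiac excitation, inflammation, interferon, antigen presentation and glucocorticoid and FOXO targets, did not pass (adjusted p from 0.607 to 0.875). Nor did the lists of ventricular and atrial cardiomyocytes, skeletal muscle, white and brown adipocytes, smooth muscle, neutrophils, T and NK cells, B cells, erythroid cells, Schwann cells and neurons, mesothelium, lung, liver and thymus (adjusted p from 0.165 to 0.962). In every list that passed in any comparison, the median and the mean of its genes had the sign of the test. Among the lists that did not pass in this average, the median or the mean had the opposite sign for PPAR targets, branched-chain amino acids, cholesterol, lipogenesis, excitation, inflammation, glucocorticoid and FOXO targets, skeletal and smooth muscle, Schwann cells and neurons, lung and liver.

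In WT hearts, transcripts of 6 of 19 measured fatty acid oxidation genes rose on HFD, and 15 over the list alone. They were led by Acads (0.37 ± 0.07), the very long chain acyl-CoA dehydrogenase gene Acadvl (0.33 ± 0.06), Acaa2 (0.32 ± 0.05) and Cpt2 (0.31 ± 0.05). Fatty acid oxidation was higher as a set (adjusted p = 2.03e-19, but adjusted p = 0.0614 with an estimated correlation). None of the 19 passed singly without WT chow replicates 2 and 4 or with the immediate early gene mean as a covariate, and the set kept adjusted p = 1.37e-10 and 7.79e-15. Arntl was 2.70-fold lower on HFD (-1.43 ± 0.26, adjusted p = 0.0245) and Cdkn1a 2.46-fold lower (-1.30 ± 0.23), each in all 4 HFD hearts against all 4 chow hearts. The call of Arntl was lost without WT chow replicate 1 (adjusted p = 0.0720) or WT HFD replicate 2 (0.0603), 3 (0.0622) or 4 (0.0670), with differences from -1.36 to -1.42. In all, 78 genes differed, 41 higher and 37 lower on HFD.

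Wee1, a clock-controlled kinase, rose by 0.79 ± 0.15. The E-box list was higher on HFD in WT hearts with 1 of 13 genes passing and 8 over the list alone (adjusted p = 1.70e-05, but adjusted p = 0.369 with an estimated correlation). Of the 7 REV-ERB-repressed genes Arntl fell, 3 were lower and 1 higher over the list alone, and the list did not pass (adjusted p = 0.0895). The phosphodiesterase gene Pde11a (0.61 ± 0.10), the growth factor gene Bmp4 (0.53 ± 0.10) and the soluble epoxide hydrolase gene Ephx2 (0.53 ± 0.06) rose. So did the sodium channel subunit gene Scn4b (0.52 ± 0.08), the gluconeogenic gene Fbp2 (0.50 ± 0.10) and Vwa8 (0.48 ± 0.06). Of 20 lipogenesis genes Gpam (0.49 ± 0.09) and Me1 (0.47 ± 0.06), which encode a glycerol-phosphate acyltransferase and malic enzyme, rose, as did the PI3-kinase subunit gene Pik3r1 (0.41 ± 0.06). None of 18 PPAR targets passed singly and 2 rose over the list alone, with Cd36 (0.15 ± 0.04) and Acot1 (0.48 ± 0.15) at the smallest p. These targets were higher as a set (adjusted p = 2.88e-05, but adjusted p = 0.210 with an estimated correlation). Scgb1c1 (-1.04 ± 0.19), the complement gene C7 (-0.90 ± 0.18), the endothelial repressor gene Bcl6b (-0.83 ± 0.13), Cldn5 (-0.81 ± 0.17), Slc41a3 (-0.76 ± 0.13) and the amino acid transporter gene Slc7a1 (-0.67 ± 0.12) fell. Falls were also seen for Mmp14 (-0.45 ± 0.08), Tgfb1 (-0.30 ± 0.05) and the gap junction gene Gja1 (-0.36 ± 0.07).

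Immune and early response lists were lower on HFD in WT hearts. Of 25 immediate early genes Egr2 fell (-0.49 ± 0.09), with 7 lower and 1 higher over the list alone. As a set they were lower (adjusted p = 1.52e-08, but adjusted p = 0.369 with an estimated correlation). Lists of antigen presentation (0 of 14 passed, 3 fell over the list alone, adjusted p = 2.96e-05), inflammation (0 of 30, 3 over the list alone, 0.000173) and interferon-stimulated genes (0 of 24, 0 over the list alone, 0.0236) were lower. They had adjusted p = 0.369, 0.369 and 0.651 with an estimated correlation. These move with WT chow replicate 2, which had the highest interferon, antigen and macrophage values of all 16 hearts (0.44, 0.69 and 0.36). Without it the interferon list turned to higher (adjusted p = 0.660), inflammation was lost (0.0579) and antigen presentation kept 0.0447. The interferon call was also lost without WT HFD replicate 3 (0.130). Endothelial markers were lower (1 of 14 fell, 4 over the list alone, adjusted p = 0.00104, but adjusted p = 0.362 with an estimated correlation). Fibroblast markers were higher (0 of 14, 2 over the list alone, adjusted p = 0.00104, but adjusted p = 0.519 with an estimated correlation), a call lost without WT HFD replicate 2 (0.0970). Stretch-responsive genes were lower with 0 of 18 passing and 2 over the list alone (adjusted p = 0.0104, but adjusted p = 0.463 with an estimated correlation). They were lost without WT chow replicate 3 (0.0824) or WT HFD replicate 3 (0.0750). Rcan1 (-0.62 ± 0.14) and the natriuretic peptide gene Nppb (-1.13 ± 0.29) had the smallest p in that list. Without WT chow replicates 2 and 4 together the interferon and fibroblast lists were lost (adjusted p = 0.974 and 0.102). In that setting, with 2 WT chow mice left and at the preset correlation, glucose use (7.13e-06), cholesterol (0.0159) and ventricular cardiomyocyte (0.0287) genes were lower and brown adipocyte markers higher (0.0159). With the immediate early gene mean as a covariate the interferon and inflammation lists were lost (0.521 and 0.490).

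Of the 78 genes 77 had no overlap between the groups, and over all genes 1175 (5.30%) had none, against 2.86% by chance. The count was 28, 41 and 43 without WT HFD replicate 4, 1 or 2, 31 and 36 without WT chow replicate 4 or 1 and 50 without Clock HFD replicate 2. It fell to 11 without WT chow replicates 2 and 4 together and to 12 with the immediate early gene mean as a covariate. Since the first of these settings leaves only 2 WT chow mice, lost precision alone may lower its count. Of the named genes, 8 of 26 (Acaa2, Cpt2, Ephx2, Me1, Pde11a, Pik3r1, Scn4b and Vwa8) kept adjusted p under 0.05 whichever array was left out.

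In Clock hearts, transcripts of 3 of 19 fatty acid oxidation genes rose on HFD. Acadvl (0.32 ± 0.06), Hadha, a subunit of the trifunctional protein (0.30 ± 0.05), and Acaa2 (0.29 ± 0.05) rose, and 16 genes over the list alone. With the immediate early gene mean as a covariate 1 rose. The list was higher with the preset (adjusted p = 2.11e-24) and with an estimated correlation (adjusted p = 0.0267). The difference from the list's change in WT hearts did not pass (interaction adjusted p = 0.797). The largest changes were a rise of Mthfd2, a mitochondrial folate enzyme (0.73 ± 0.10), and a fall of C7 (-1.07 ± 0.18). In all 20 genes differed, 11 higher and 9 lower on HFD. None of the 20 clock genes measured was among them, Arntl lying at -0.24 ± 0.26 (adjusted p = 0.889). That error pools all groups. The SD of Arntl was 0.15 on chow and 0.06 on HFD in Clock hearts, against 0.78 in WT chow hearts. Its values in Clock hearts did not overlap (0.12 to 0.43 on chow, -0.05 to 0.09 on HFD), as held for 5.31% of all genes. A small fall of Arntl is therefore not excluded.

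Scn4b (0.56 ± 0.08), Ephx2 (0.48 ± 0.06), Vwa8 (0.45 ± 0.06), the peroxisomal beta-oxidation gene Hsd17b4 (0.36 ± 0.06) and the asparaginyl-tRNA synthetase gene Nars (0.35 ± 0.06) rose. The anticoagulant gene Tfpi (-0.52 ± 0.08), Krt222 (-0.48 ± 0.08), the antigen-presenting gene Mr1 (-0.47 ± 0.07) and Dad1 (-0.45 ± 0.08) fell, as did the phospholipase gene Pla2g2d (-0.38 ± 0.07), Tgfb1 (-0.36 ± 0.05) and the arginine methyltransferase gene Prmt5 (-0.34 ± 0.06). PPAR targets were higher with 0 of 18 passing and 10 over the list alone (adjusted p = 7.54e-08, but adjusted p = 0.0530 with an estimated correlation). Pdk4, which restrains glucose oxidation (0.76 ± 0.16), and the lipid droplet gene Plin2 (0.26 ± 0.06) had the smallest p. Glucocorticoid and FOXO targets were higher (0 of 20 passed, 3 over the list alone, adjusted p = 0.00175, but adjusted p = 0.490 with an estimated correlation), a call lost without Clock chow replicate 1 (0.0755). Antigen presentation (0 of 14, 0 over the list alone, adjusted p = 0.0225) and macrophage markers (0 of 14, 1 over the list alone, 0.0345) were lower, with adjusted p = 0.699 and 0.568 with an estimated correlation. The first was lost without Clock chow replicate 4 (0.143) or Clock HFD replicate 1 (0.108), and the second without Clock chow replicate 1 (0.0971) or 4 (0.217) or Clock HFD replicate 1 (0.298) or 2 (0.0542). Both were lost with the immediate early gene mean as a covariate (0.0860 and 0.125). The interferon list was lower (0.0110) and autophagy higher (0.0268) without WT chow replicates 2 and 4.

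All 20 genes had no overlap between the groups, and over all genes 1178 (5.31%) had none, against 2.86% by chance. The count was 6, 8 and 8 without Clock HFD replicate 3, 2 or 4, 7, 10, 9 and 9 without Clock chow replicate 1, 2, 3 or 4 and 13 without WT HFD replicate 2. Of the named genes, 5 of 17 (Ephx2, Mthfd2, Scn4b, Tgfb1 and Vwa8) kept adjusted p under 0.05 whichever array was left out.

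**Figure D3:**
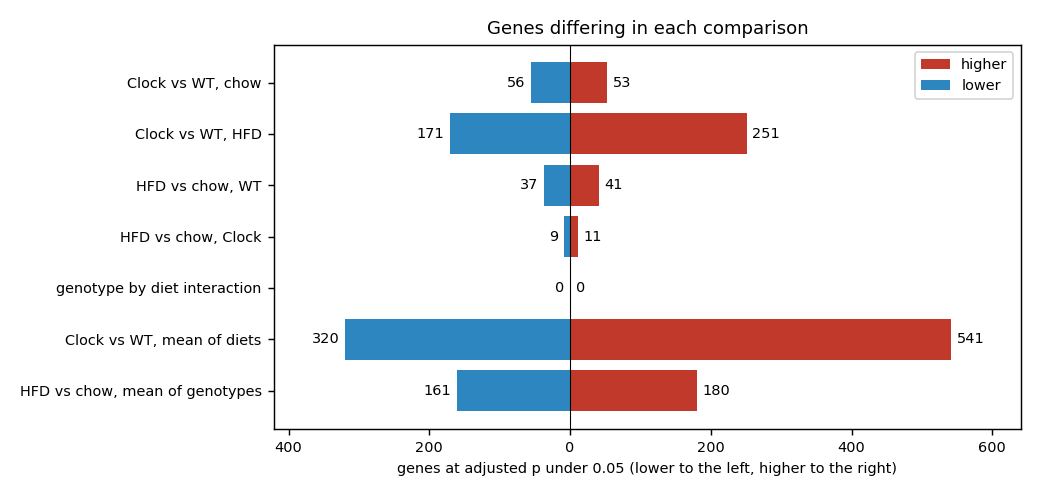
Genes at adjusted p under 0.05 in each of the 7 comparisons, with those higher drawn to the right and those lower to the left. The genotype moved more genes on HFD (251 higher, 171 lower) than the diet moved in WT hearts (41 and 37) or in Clock hearts (11 and 9), and the interaction has 0 genes.

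Whether the mutation altered the response to HFD was tested by the interaction of genotype and diet, and no single gene passed it. Limma called 0 genes (smallest adjusted p 0.15), with 1122 at an unadjusted p under 0.05, and 0 under each alternative tried. The smallest p were those of Wipf3 (-0.45 ± 0.07), A730017L22Rik (-0.40 ± 0.07), Parp8 (-0.44 ± 0.09), Dpy19l3 (0.40 ± 0.08) and Gm10272 (-0.61 ± 0.13), none of which passed. The difference of Arntl between the diet effects, 1.20 ± 0.36, did not pass either (adjusted p = 0.793), so the diet effect on Arntl in WT hearts is not shown to differ from that in Clock hearts. As sets, 6 lists passed with the preset correlation, and each had adjusted p = 0.846 with an estimated correlation and 0.899 with fry. The E-box list responded less upward to HFD in Clock hearts (adjusted p = 0.000701), with Wee1 (-0.64 ± 0.21) and Per3 (-0.55 ± 0.21) at the smallest p, and was lost without WT chow replicate 4 (0.0763) or without replicates 2 and 4 (0.259). More upward in Clock hearts were stretch-responsive genes (0.000701), with Acta1 (1.57 ± 0.44) and Nppb (0.87 ± 0.41), and immediate early genes (0.00214). Without Clock chow replicate 4, where Nppb lay at -1.07, its difference was 0.47. More upward too were heat shock (0.0193), glucose use (0.0298) and glucocorticoid and FOXO targets (0.0384), with Cdkn1a (1.35 ± 0.33). No member of the 6 lists passed over all genes, and over the list alone only 1 stretch-responsive gene and 1 glucocorticoid and FOXO target did. Immediate early genes were lost without WT HFD replicate 4 (0.135) or Clock HFD replicate 3 (0.279). Heat shock was lost without WT chow replicate 3 (0.113), Clock chow replicate 4 (0.194) or Clock HFD replicate 2 (0.166), and so were glucose use and glucocorticoid and FOXO targets with 7 and 9 of the 16 arrays (highest adjusted p 0.222 and 0.409). With the immediate early gene mean as a covariate glucocorticoid and FOXO targets were lost (0.467). Ventricular cardiomyocyte markers (0.0288, more upward) and macrophage markers (0.0303, less upward) passed without WT chow replicates 2 and 4.

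The diet effects in WT and in Clock hearts share no array. Of the 78 and 20 genes, 8 were called in both. Of these 6 were higher and 2 lower on HFD and 0 in opposite directions, where independent lists would share 0.0203 and 0.0150. Here too the shared estimate of spread can raise the overlap. Ephx2, Scn4b, Vwa8, Acadvl, Acaa2 and Hadha rose in both and C7 and Tgfb1 fell in both. Over all genes the diet differences correlated at r = 0.35 (rho = 0.26), again across genes.

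Averaged over the genotypes, HFD changed 341 genes, 180 higher and 161 lower. Fatty acid oxidation (13 of 19 rose, 18 over the list alone) and PPAR targets (4 of 18 rose, 8 over the list alone) were the lists that passed both with the preset correlation (adjusted p = 1.34e-27 and 4.55e-09) and with an estimated one (adjusted p = 0.0165 and 0.0322). The fatty acid genes rose by small steps, from 0.14 ± 0.03 for Etfa to 0.33 ± 0.05 for Acads, and the PPAR targets Pdk4 (0.55 ± 0.11), Acot1 (0.44 ± 0.10), Plin2 (0.22 ± 0.04) and the fatty acid transporter gene Cd36 (0.14 ± 0.03) rose with them. In these lists 9 genes and 1 gene rose without WT chow replicates 2 and 4 together, and with the immediate early gene mean as a covariate 9 and 0. Arntl was lower (-0.84 ± 0.18) and Wee1 higher (0.47 ± 0.11).

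**Figure D4:**
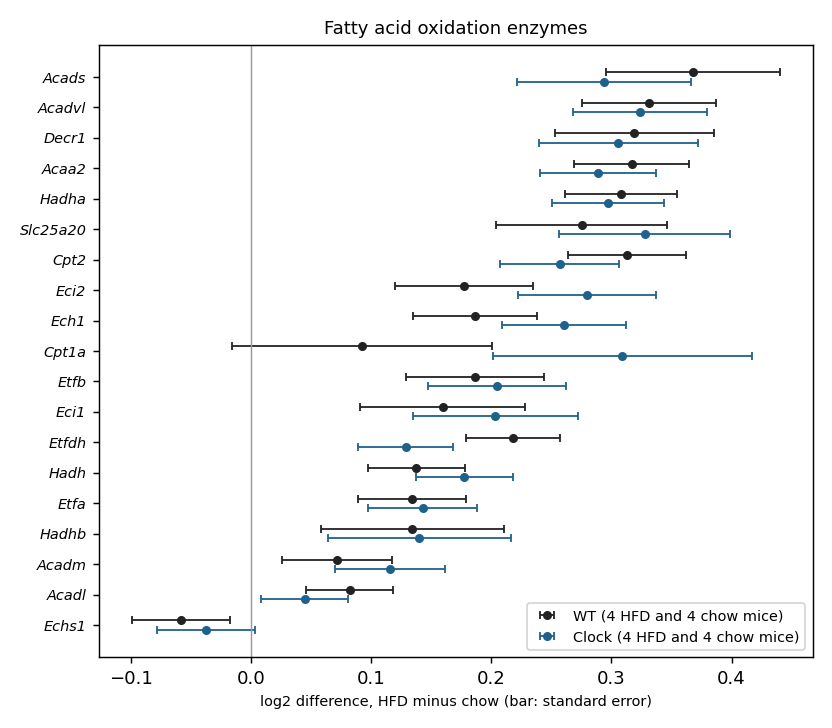
Log2 difference between HFD and chow for the 19 fatty acid oxidation genes in WT (black) and Clock hearts (blue), with the standard error of the fit from 4 HFD and 4 chow mice per genotype. All but Echs1 lie above 0 in both genotypes, with Acadvl at 0.33 in WT and 0.32 in Clock hearts.

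On HFD in this average rises were also seen for Gpam (0.49 ± 0.07), Me1 (0.34 ± 0.04), the retinol saturase gene Retsat (0.39 ± 0.06) and the potassium channel subunit gene Kcnv2 (0.42 ± 0.08). They were also seen for Mylip, the ligase that degrades the LDL receptor (0.36 ± 0.05), Qars (0.35 ± 0.06) and the lipid droplet enzyme gene Hsd17b11 (0.35 ± 0.07). Lgals9 (-0.58 ± 0.11), Pdlim1 (-0.43 ± 0.06), B4galt1 (-0.39 ± 0.07), the proteasome activator gene Psme1 (-0.38 ± 0.07), Epha4 (-0.37 ± 0.07), Gja1 (-0.32 ± 0.05) and Tgfb1 (-0.33 ± 0.03) fell, and the matricellular gene Postn rose (0.34 ± 0.07). The cytokine genes Il1b (-0.57 ± 0.13) and Tnf (-0.33 ± 0.07) fell among 30 inflammation genes (3 over the list alone). Inflammation was lower as a set (adjusted p = 0.000372, but adjusted p = 0.350 with an estimated correlation).

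Lower on HFD in the average were also the lists of antigen presentation (0 of 14, 2 over the list alone, adjusted p = 2.20e-05), interferon (0 of 24, 0 over the list alone, 0.00535), macrophages (0 of 14, 2 over the list alone, 0.0250) and immediate early genes (1 of 25 fell, 6 over the list alone, 5.09e-07). The same held for proliferation (0 of 28, 0 over the list alone, 0.0356), cholesterol (1 of 16 fell, 1 over the list alone, 0.0358), endothelium (3 of 14 fell, 4 over the list alone, 0.00786) and mesothelium (1 of 9 fell, 1 over the list alone, 0.0250). With an estimated correlation these 8 lists had adjusted p = 0.350, 0.538, 0.585, 0.350, 0.350, 0.350, 0.310 and 0.248. Higher were the E-box list (1 of 13 rose, 5 over the list alone, adjusted p = 0.00137), fibroblast markers (1 of 14, 2 over the list alone, 0.00786) and glucocorticoid and FOXO targets (2 of 20 rose, 5 rose and 2 fell over the list alone, 0.0356). They had adjusted p = 0.443, 0.410 and 0.443 with an estimated correlation. Without WT chow replicate 2 the interferon, macrophage, proliferation and cholesterol lists were lost (adjusted p = 0.316, 0.467, 0.118 and 0.0596). Leaving out 1 other array also ended the calls of macrophages, proliferation, cholesterol, endothelium, mesothelium and glucocorticoid and FOXO targets, with 5, 4, 5, 1, 2 and 5 of the 16 arrays in all. Without WT chow replicates 2 and 4 together the interferon (0.118), macrophage (0.301), proliferation (0.111), mesothelium (0.0830), E-box (0.0754), fibroblast (0.0601) and glucocorticoid and FOXO lists (0.111) were lost. In that setting glucose use was lower (0.0128) and brown adipocyte markers higher (0.0144). With the immediate early gene mean as a covariate the interferon (0.200), macrophage (0.224), cholesterol (0.348), endothelium (0.0715), mesothelium (0.308) and inflammation lists (0.348) were lost. The remaining pathway lists did not pass (adjusted p from 0.0573 to 0.922), nor did those of the other cell types (0.0754 to 0.919). Among these the median or the mean had the opposite sign of the test for endoplasmic reticulum stress, insulin and AKT, ventricular and atrial cardiomyocytes, skeletal muscle, and Schwann cells and neurons. The count of 341 was 218 without Clock HFD replicate 4, 222 without Clock HFD replicate 2 and 141 without WT chow replicates 2 and 4 together. It was 107 with the immediate early gene mean as a covariate.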

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

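The tests of explanations in this part were chosen after the results were seen, except the splits of the mice, which were planned.

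In WT hearts Arntl was lower on HFD than on chow by log2 -1.43, and 1 chow mouse, replicate 4, had a high value of 0.54. Without that mouse the difference was -1.10 with a 95% interval from -1.48 to -0.73 (upper bound -0.727). The fit pools the spread of all groups, while the SD of Arntl was 0.78 in WT chow hearts and 0.06 to 0.24 in the others. The interval can therefore be too narrow, and it cannot decide whether 1 mouse out of step is the whole cause. The remaining chow hearts (-0.32, -0.66 and -1.34) still lay above every WT HFD heart (highest -1.54). Without replicates 2 and 4 the difference was -1.05, with an interval of the same kind from -1.49 to -0.61 and an adjusted p of 0.0978. Differences in clock time between the mice of a group stay open: the main direction of spread among WT chow hearts held 93.3% of the variance of 20 clock genes and correlated across genes with the diet difference at r = 0.755 (rho = 0.617). Since 1000 simulations with no diet effect gave a median of 0.922 (5th to 95th percentile 0.229 to 0.997), this r cannot decide, and a shift of clock phase by the diet, untested here, may give the same picture.

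In WT chow replicate 2 the interferon list lay far from the other 3 mice (gap over range 0.854), as did the T and NK cell list (0.895). In that heart 8 genes lay more than 4-fold above the mean of the others, with rises from 2.17 to 5.07 on the log2 scale, Gm4841 highest. The 14 macrophage markers rose there by 0.104 to 0.793 (median 0.333), so the lowest of the 8 lay 1.37 above the highest marker. The 8 were picked for their rise in this same heart, so the gap follows partly from the choice. It cannot decide whether that piece of heart held a larger share of macrophages. Against the other 3 mice the whole interferon list was higher by 0.486 and the macrophage list by 0.410. The difference of 0.0762 lies within the range of the other 15 hearts (-0.138 to 0.157), so a larger share of macrophages stays open. No biological explanation was tested, since the design names none for 1 mouse of a group.

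Extracellular matrix, fibroblast and endothelial lists were higher in Clock than in WT hearts by camera at the preset correlation, and the first 2 share genes. With an estimated correlation the matrix list passed in the average over diets (adjusted p 0.0246), the fibroblast (0.306) and endothelial (0.0884) lists did not, and none of the 3 passed on either diet alone. A lower share of cardiomyocytes would raise the markers of every other cell type alike. On HFD endothelial markers rose above macrophage markers by 0.336, and by 0.309 to 0.392 without any 1 heart. The exact two-sided permutation p was 0.0286, the lowest that 70 regroupings allow, which argues against such a lower share as the whole cause on HFD. On chow the difference of 0.156 (exact permutation p = 0.371) was 0.0385 without WT chow replicate 2, so a lower share stays open there too. Ventricular cardiomyocyte markers differed in Clock hearts by 0.0194 on chow and 0.0521 on HFD. Smooth muscle markers differed by -0.00724 and -0.00817, and atrial cardiomyocyte markers by -0.133 and -0.0814. The WT chow hearts that stand apart do not enter the HFD comparison, where the median of the matrix list was still 0.189 higher, which argues against them as the whole cause. A change in the matrix-producing and endothelial cells of the Clock hearts, by genotype, may underlie the difference and stays a hypothesis.

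In 6 of the 7 comparisons the real grouping of the mice gave more genes than every other split tried, which argues against chance. Ranking first is the most that 35 or 100 splits can show, so chance is not excluded. In 1 of 35 splits, the real one, as many genes passed as for Clock against WT on chow (109, highest other 1), on HFD (422, highest other 0), and for HFD against chow in WT (78, highest other 2) and in Clock hearts (20, highest other 1). In 1 of 100 drawn splits, again the real one, as many passed in the average over diets (861, highest other 238) and over genotypes (341, highest other 22). For the interaction, 39 of 100 splits gave at least the 1122 genes found at an unadjusted p under 0.05 (median of the others 1009, highest 2314). These splits reassigned diets within each genotype, which can turn part of the diet effect into an interaction. They therefore cannot decide, and chance stays open.

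Other single hearts lay far from the 3 others of their group. By gap over range these were heat shock genes in Clock chow replicate 3 (0.864), proliferation (0.880), macrophage (0.862) and lung (0.882) genes in WT HFD replicate 3, smooth muscle in WT HFD replicate 2 (0.854) and mesothelium in Clock chow replicate 4 (0.861). Among clock genes they were Per3 (0.906) and Dbp (0.834) in WT HFD replicate 1, Ciart in Clock chow replicate 4 (0.889), Rora in WT chow replicate 4 (0.927) and E2f8 in WT HFD replicate 2 (0.870). In all, 8 of 164 list groups and 5 of 80 clock gene groups lay so far out, where chance gives about 1 in 20.

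The diet effects of 6 lists differed between genotypes by camera at the preset correlation, with median interactions of -0.27 for E-box genes, 0.0575 for glucose use, 0.16 for stretch-responsive genes, 0.10 for heat shock, 0.12 for glucocorticoid and FOXO targets and 0.23 for immediate early genes, none of which passed with an estimated correlation (adjusted p 0.846). Outside the genes tested, 10830 probe sets lack a single symbol, and 167 of them passed for the genotype and 65 for the diet in the averages.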

How the results depend on the processing

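Leaving out the WT chow arrays 2 and 4 and the immediate early gene covariate were chosen after seeing the data, and the other alternatives were planned. Without arrays 2 and 4 only 2 WT chow mice remain, so a lower count there may come from lost precision. The immediate early list itself differed between groups by camera at the preset correlation. That covariate can therefore remove part of a genotype or diet difference, and a call lost with it does not show the cause. None of the 428 named gene results changed direction past the threshold (0 reversed), and 111 of 268 that passed did so under every alternative run. In the order Clock against WT on chow, on HFD, HFD against chow in WT, in Clock, interaction, genotype average and diet average, the genes were 109, 422, 78, 20, 0, 861 and 341, and the lists 8, 13, 10, 5, 6, 16 and 14. The interaction had 0 genes under each alternative run. With all probe sets the genes were 120, 481, 54, 30, 0, 974 and 373, and with the highest-mean probe set 107, 412, 78, 20, 0, 860 and 333.

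With trend and robust, whose trend runs on mean values that centring has emptied, genes were 59 on chow, 40 for diet in WT and 8 for diet in Clock hearts. Array weights gave 53 and repeated quantile normalization 36 for diet in Clock hearts. With only the 8 arrays compared they were 38 on chow, 427 on HFD, 15 for diet in WT and 7 in Clock hearts. A replicate block gave 41 for diet in WT and 12 in Clock hearts. Equal numbers showed little sign of pairing: residual correlations ran from -0.149 to 0.163, 3 of 24 above 0.1. Among arrays of the other groups, 7 of 16 arrays correlated best with one of their own number, so some pairing is not excluded. Lists fell to 0, 1, 0, 1, 0, 2 and 2 with an estimated correlation and to 3, 4, 1, 2, 0, 7 and 4 with fry. Without WT chow arrays 2 and 4, genes were 49 on chow, 11 for diet in WT, 507 in the genotype average and 141 in the diet average, and lists 10 and 9 in the averages. With the immediate early gene covariate, genes were 280 on HFD, 12 for diet in WT and 107 in the diet average, and lists 8 on HFD, 3 for diet in Clock hearts and 7 in the diet average. For changes whose cause no construction explains, the cause was not tested.

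Leaving out 1 array gave 49 (without WT chow replicate 2 or Clock chow replicate 1) to 144 genes on chow, 241 (Clock HFD replicate 2) to 490 on HFD, 28 (WT HFD replicate 4) to 90 for diet in WT, 6 (Clock HFD replicate 3) to 27 for diet in Clock hearts, 648 to 1003 in the genotype average and 218 (Clock HFD replicate 4) to 329 in the diet average. Lists ran from 6 to 13, 10 to 13, 9 to 13, 4 to 13, 3 to 8, 11 to 16 and 9 to 18. The dim gene filter was not run, since the centred values hold no signal over background, and what low signal limits is unknown.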

Other observations

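Stress and activity genes varied between hearts of the same group. Hspa1a, a heat shock chaperone gene, reached 3.05 in Clock HFD replicate 2 and 2.89 in Clock chow replicate 3. In WT HFD replicate 4 the nuclear receptor genes Nr4a1 (-2.29) and Nr4a3 (-2.59) and the matricellular gene Thbs1 (-1.88) had the lowest values of all 16 hearts. The Y-linked genes Uty (-0.91) and Kdm5d (-0.65) had their lowest values in Clock HFD replicate 4, where Eif2s3y (-0.75) had its second lowest, after -1.11 in WT chow replicate 1. These genes were chosen after their values were seen.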
